A study of Mus musculus with 23 samples.

How the data were processed

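Messenger RNA was measured by sequencing in 23 libraries from mouse hippocampus. Per the labels, messenger RNA was taken with oligo(dT) beads in both batches, and batch 1 was sequenced with single-end reads of 50 bases. The deposited table holds 1 RPKM value per gene and library, that is reads per kilobase of gene scaled to the mapped reads of the library, computed by the authors and rounded to 2 decimals. The same table holds the authors' own log2 fold change of each of the 6 comparisons of groups, and a p-value and an adjusted p-value of each, also deposited by the authors, whose test and adjustment are not given in the sources used here. Those columns were used to count the authors' calls beside those made here and to give some of their log2 fold changes beside those computed here. Per the submitters' processing notes, reads were aligned with HISAT to the mouse genome build mm10. No version of HISAT is given, and how reads were counted and which library size and gene length entered the RPKM is not given in the sources used here. The raw reads were not analysed here.

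Of 21785 genes in the table, 2721 had no value in any library and 19064 had values. RPKM summed to between 353904 and 373054 per library. Depth was estimated from the steps between low values in 425 genes with transcripts shorter than 1000 bases and a mean RPKM below 0.3. The estimate was the number of reads, among those tried, that brought the values nearest to whole numbers by a mean cosine score. At that number between 67.3% and 81.9% of values lay within 0.15 read of a whole number. At a depth fixed beforehand 30% would by chance, and the chance rate after choosing the best depth was not computed. For Dp16 F2 and M4 the best estimate was a multiple of a smaller one that did nearly as well, and a rule for that case, added after the estimates were seen, took the smaller. The estimates ran from 14.65 to 17.25 M reads with a median of 16.7 in batch 1 and 16.65 in batch 2, and no counting interval was computed from them. Correlations between libraries ran from 0.965 to 0.993.

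Libraries were grouped by the genotype in their labels, and batch was taken from the molecule label and the extraction protocol, sex from the letter in the title. RPKM was put on the log2 scale after adding 0.1, and 13971 genes with a mean over all libraries of at least 0.5 were tested. The test was limma 3.58.1 in R 4.3.3 with an intensity trend in the spread, all 4 groups in 1 model with batch and sex letter as covariates, a two-sided moderated test and Benjamini-Hochberg adjustment over the genes tested in each comparison. A gene was called at an adjusted p under 0.05. The 6 comparisons were those of the labels, and differences of the effect of Dp16 by sex letter and by batch were tested as interaction terms. Deviations from the group means correlated by 0.254 on average over 26 pairs of libraries with the same replicate label and batch, 21 of them over 0.1, and by 0.254 over 26 pairs with other labels of the same batch and sex letter, so the replicate numbers were not taken to pair the samples. Genomic positions came from the deposited table and were read as positions in mm10, the build of the alignment, and 35 genes spanning over 3 Mb there were given no position.

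The duplicated segment was a list of 107 symbols, of which 98 had values and 81 were tested. A further 33 lists of markers and pathways, each with at least 4 tested members, were compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over the lists of each comparison. The estimated correlation and fry, which asks whether a list moves 1 way without comparing it with other genes, were alternatives. The covariance of the change from WT to Dp16 with the change from Dp16 to a corrected group was computed with the Dp16 libraries in disjoint parts, averaged over 36 such splits, and compared with 1000 permutations of the residuals. Overlaps between contrasts with WT were compared with splits of the WT libraries, and correlations between them also with simulated groups that share controls.

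The genes named are Dyrk1a and Kcnj6 in every comparison. In each comparison they also include the 10 higher and 10 lower called genes outside the segment with the largest log2 change among those with a mean RPKM of at least 1, and the 5 called with the smallest adjusted p. In Dp16 against WT they include the 10 segment genes with the largest and the 5 with the smallest change at that level. Of each list they include the 4 members with the smallest p and any called member, of which those of called lists are given, and predicted genes were left unnamed. Some genes that the rule names are not reported here. The lists, the naming rule, the model and its tests were fixed before the data were examined, while the batch score and some tests of explanations, named with the flagged results, were chosen after seeing them. So were 5 of the alternatives: sex and batch of the WT libraries F1 and M3 as expression shows them, those libraries left out, the mean of the choroid plexus or of the myelin markers as a covariate, and the circadian list with an estimated correlation and each library left out.

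The other alternatives were a pseudocount of 0.01 or 0.5, no filter or a mean RPKM of at least 1, scaling by the median ratio, quantile normalization, array quality weights, no batch or no sex covariate, each batch alone, the replicate label as a block, the compared groups alone in the fit, a fold threshold of 1.2, the segment by position, and each library left out in turn. The model was also tested on simulated data with 200 changed genes among the 13971. At a 2-fold change it called between 90.9% and 98.5% of them in the right direction, at 1.5-fold between 77.6% and 91.0%, and at 1.25-fold between 41.8% and 58.2%, over the 6 comparisons. Unchanged genes made up between 2.5% and 7.51% of the calls. The simulated noise was drawn independently for each gene and library, with the batches as labelled. These rates therefore leave out any variation that genes share across the real libraries and any library that runs against its label. The median log2 change of all tested genes lay between -0.01 and 0.02 in every comparison.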

Results

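The series measured messenger RNA by sequencing in the hippocampus of mice, and each library is labelled with a genotype, a letter for sex and a replicate number. There were 5 WT libraries, 7 Dp16 libraries, 6 libraries labelled Dp16/D-KO and 5 libraries labelled Dp16;D-KO/K-KO, 23 in all. Dp16 mice carry an extra copy of the segment of chromosome 16 whose genes have their human orthologues on chromosome 21, and they serve as a model of Down syndrome. D-KO and K-KO stand for the removal of a copy of Dyrk1a and of Kcnj6, which the title of the series describes as normalization of both genes. The libraries form 2 batches by their labels. Batch 1 has 10 libraries, given as total RNA on a C57BL/6 background at 2 to 3 months of age, and batch 2 has 13 libraries, given as polyA RNA on a background of more than 90% C57/B6. WT and Dp16;D-KO/K-KO each have 2 libraries in batch 1 and 3 in batch 2, Dp16 has 3 and 4, and Dp16/D-KO has 3 and 3. Each value below is a group mean of RPKM with its SD, and each comparison used limma with batch and sex letter in the model.

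No counts are among the values used here, so the depth was read from the smallest steps between low RPKM values, which gave 14.65 to 17.25 M reads per library with a median of 16.7. In WT the estimates were 16.7 M reads for F1, 16.8 for F2, 16.65 for M2 and for M3, and 14.65 for M4. In Dp16 they were 16.5 M reads for F1, 17.05 for F2, 17.25 for F3, 17.1 for M1, 17.2 for M2, 15.4 for M3 and 14.95 for M4. In the libraries labelled Dp16/D-KO they were 16.65 M reads for F1, 17 for F2, 16.7 for F3, 17 for M1, 16.6 for M2 and 16.35 for M3. In those labelled Dp16;D-KO/K-KO they were 16.5 M reads for F1, 16.45 for F2, 16.7 for M1, 16.8 for M2 and 16.85 for M3. Of 21785 genes, 19064 had values and 13971 had a mean RPKM of at least 0.5 and were tested. The WT library F1 had 12.65 RPKM of the Y-linked gene Ddx3y, while no other library with the letter F had over 0.03, and the WT library M3 had 0.01. By a score of genes that differ between the batches, WT M3 (0.0866) lies with the libraries of batch 1 (up to 0.0695) and not with those of batch 2 (0.945 or more), where its label puts it. Values within a batch against WT below keep M3 in batch 2 as labelled. Because these 2 libraries run against their labels, each count of genes is also given without them, an alternative chosen after the data were seen.

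Dyrk1a, a protein kinase gene, and Kcnj6, the gene of an inwardly rectifying potassium channel subunit, were the genes targeted in the corrected groups. Dyrk1a lies at positions 94569098 to 94698689 of chromosome 16 and Kcnj6 at 94748683 to 94997696 (mm10). Dyrk1a RPKM was 16.9 ± 1.19 in WT (n = 5), 24.3 ± 1.48 in Dp16 (n = 7), 24.3 ± 2.08 in the libraries labelled Dp16/D-KO (n = 6) and 24.7 ± 1.46 in those labelled Dp16;D-KO/K-KO (n = 5). Kcnj6 RPKM was 18.3 ± 1.87, 26.9 ± 3.48, 26.0 ± 1.52 and 25.6 ± 1.67 in the same order. Neither gene was detectably lower in the libraries whose labels name its removal. Against Dp16, the log2 change of Dyrk1a was -0.01 (95% interval -0.09 to 0.08, adjusted p = 0.935) in the libraries labelled Dp16/D-KO and 0.02 (-0.07 to 0.11, adjusted p = 0.889) in those labelled Dp16;D-KO/K-KO. The change of Kcnj6 in the libraries labelled Dp16;D-KO/K-KO was -0.06 against Dp16 (-0.23 to 0.10, adjusted p = 0.822) and -0.02 against those labelled Dp16/D-KO (-0.20 to 0.15, adjusted p = 0.966). A return from 3 copies to 2 in expression would be -0.58, below the lower bound of every one of these intervals. Since these values run against the labels, the corrected groups are called by their labels throughout, and a direction drawn for them is a direction of libraries so labelled. How reads were counted is not given. If they were counted over the whole gene, a copy that is transcribed but disrupted would be counted with the intact ones.

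**Figure D1:**
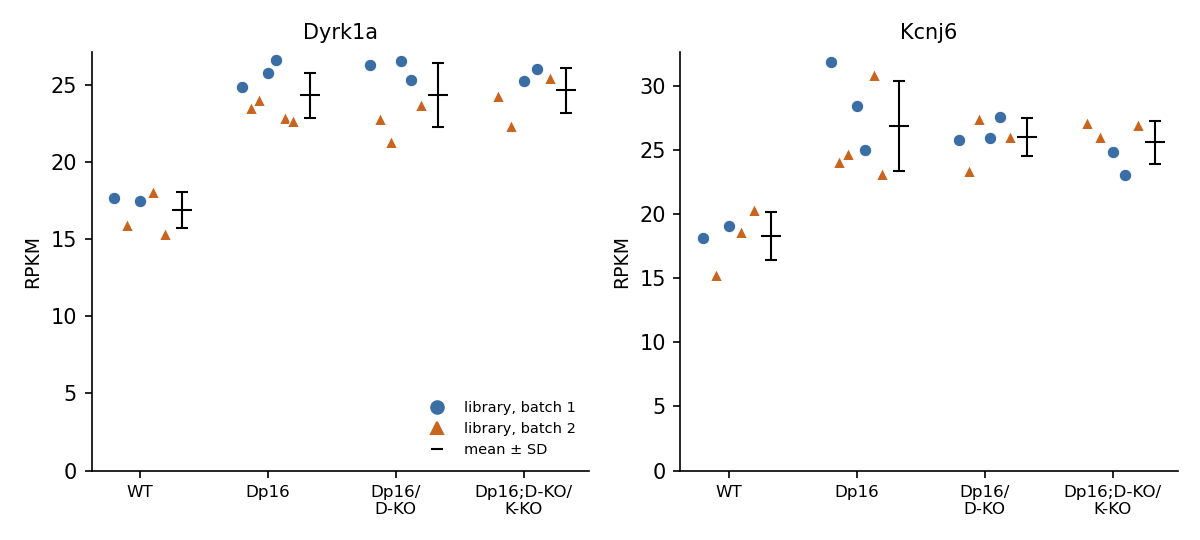
RPKM of Dyrk1a and of Kcnj6 (vertical axes, from 0) in each of the 23 libraries by group as labelled, with batch 1 as circles, batch 2 as triangles and bars for the mean and SD. Dyrk1a lay between 15.36 and 18.04 in WT, between 21.3 and 26.54 in the libraries labelled Dp16/D-KO and between 22.31 and 26.03 in those labelled Dp16;D-KO/K-KO.

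The comparison of Dp16 with WT asks what the duplicated segment changes. Genes of the segment rose together: of 79 tested segment genes other than Dyrk1a and Kcnj6, 77 had a positive change, 64 were called higher and 0 lower, and the median log2 change was 0.52, a 1.43-fold difference. The splicing factor gene Son had 72.4 ± 3.93 RPKM in Dp16 (n = 7) against 45.0 ± 4.37 in WT (n = 5; log2 change 0.69 ± 0.05 SE, adjusted p = 2.28e-08). The interferon receptor gene Ifnar2 had 21.2 ± 3.93 against 11.7 ± 2.87 RPKM (0.87, adjusted p = 8.02e-05). The kainate receptor gene Grik1 had 6.21 ± 0.585 against 3.72 ± 0.421 (0.73, adjusted p = 6.69e-06) and the cell adhesion gene Ncam2 had 14.0 ± 1.95 against 8.59 ± 1.22 (0.71, adjusted p = 8.02e-05). Dyrk1a rose by 0.52 ± 0.04 SE on the log2 scale (adjusted p = 5.62e-08; 0.54 in batch 1 and 0.51 in batch 2) and Kcnj6 by 0.55 ± 0.08 SE (adjusted p = 0.000193; 0.61 and 0.53).

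Other segment genes with the largest changes were Sh3bgr (1.13), Bace2 (1.01), Rbm11 (0.81), Adamts1 (0.78) and C2cd2 (0.71), all called, and Eva1c (0.75), which did not pass the test (adjusted p = 0.121). The Sh3bgr mean of 2.50 ± 1.99 RPKM included 1 library, Dp16 M2, far above the other 6. The smallest changes were those of Kcne2 (-0.14, adjusted p = 0.978), Ripply3 (-0.07), Setd4 (0.14), Prdm15 (0.20) and Urb1 (0.24, adjusted p = 0.12), none of them called. Kcne2, a potassium channel subunit gene of the choroid plexus, had 9.28 ± 11.2 RPKM in Dp16 against 5.25 ± 3.86 in WT. Its mean was higher but its log2 change negative, as it reached 15.42 to 25.55 RPKM in Dp16 F2, F3 and M2, which have the most Ttr of that group, and at most 0.98 in the other 4. Adjusted over the list alone, 72 of the 79 genes were higher. The segment median was 0.51 within batch 1 and 0.55 within batch 2, and the segment stood apart from all other genes with an estimated correlation (camera p = 3.24e-13). The 352 tested genes on the rest of chromosome 16 had a median of -0.02. The 34 tested genes whose human orthologues lie on chromosome 21 but which lie outside the segment had a median of 0.05 (camera p = 0.639 with an estimated correlation), of which 1 was called higher, 1 lower and 32 were not called. Fold changes are on the scale of log2 of RPKM plus 0.1, which makes those of genes near the filter smaller than they are.

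**Figure D2:**
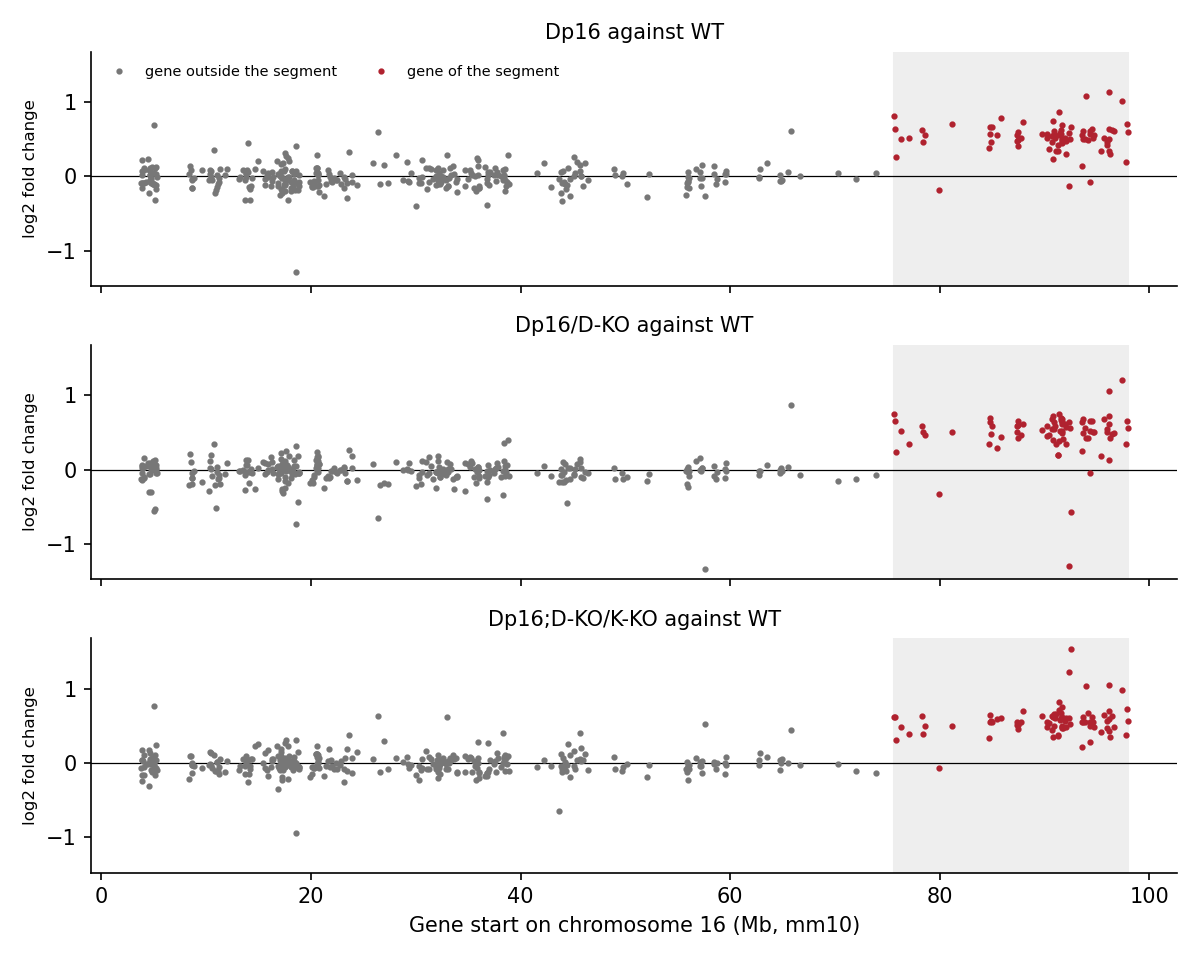
Log2 change of each tested gene on chromosome 16 (vertical axis) against its start in Mb (horizontal axis, mm10) for Dp16, for the libraries labelled Dp16/D-KO and for those labelled Dp16;D-KO/K-KO, each against WT. The shading spans the tested genes of the segment, from 75592844 to 97962623. The median of the segment genes other than Dyrk1a and Kcnj6, 79 in number, was 0.52, 0.55 and 0.55, and that of the 352 genes outside it was -0.02, -0.02 and -0.01.

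Outside the segment, 53 genes were higher and 83 lower in Dp16 than in WT, by symbol. The nonagouti gene a, which encodes a signalling protein of coat colour, rose from 0.54 ± 0.118 RPKM in WT (n = 5) to 5.14 ± 0.92 in Dp16 (n = 7), an 8.19-fold difference after adding 0.1 and adjusting for batch and letter (log2 change 3.03 ± 0.14 SE, adjusted p = 9.15e-12). In the authors' deposited table its log2 change is smaller, 1.544 here, 1.252 in the libraries labelled Dp16/D-KO and 1.447 in those labelled Dp16;D-KO/K-KO against WT. It was 2.70 in batch 1 and 3.32 in batch 2. The selenoprotein gene Selenov rose from 0.262 ± 0.0963 to 1.21 ± 0.198 RPKM (1.88, adjusted p = 2.25e-06) and Slc5a5, the sodium and iodide cotransporter gene, from 6.97 ± 0.57 to 11.9 ± 2.71 (0.73, adjusted p = 0.000314; 0.42 in batch 1 and 0.89 in batch 2). Tbx1, a transcription factor gene, fell from 0.938 ± 0.183 to 0.327 ± 0.0894 RPKM (-1.28, adjusted p = 0.000128). Cyp11a1, which makes pregnenolone from cholesterol, fell from 2.22 ± 0.229 to 1.18 ± 0.181 (-0.87, adjusted p = 5.56e-05) and Cbs, the cystathionine beta-synthase gene, from 16.0 ± 2.33 to 10.7 ± 1.3 (-0.58, adjusted p = 0.000204). Cbs has its human orthologue on chromosome 21 but lies outside the duplicated segment, on chromosome 17.

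The remaining called genes with the largest rises were Rspo1 (0.82), Ucma (0.77), Cybrd1 (0.62), Ifit3b (0.60), Pcsk4 (0.58) and Cmbl (0.56). Zfp982 (0.88) belongs to a family of near-identical zinc finger genes, so its value is uncertain. D16Ertd472e (0.55, adjusted p = 0.000145) is counted outside the list of segment symbols but lies within the segment by position. The remaining falls were Micalcl (-0.69), Aspdh (-0.63), Recql4 (-0.56), Dcdc2b (-0.52), Fndc8 (-0.52), Cpne9 (-0.51) and Zfp772 (-0.50). Among members of the fixed lists, Ccnd2, the cyclin D2 gene, fell from 17.4 ± 1.05 to 14.3 ± 1.44 RPKM (-0.29, adjusted p = 0.00502) and the CA1 marker Wfs1 rose from 40.3 ± 5.37 to 50.5 ± 5.05 (0.34, adjusted p = 0.00424). Of the microglial markers, Tmem119 fell (-0.26, adjusted p = 0.0287) and Ctss rose (0.24, adjusted p = 0.0121).

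Cell type and pathway lists were tested against all other genes, and 5 of 33 were called in Dp16 against WT by camera with a preset correlation, 0 with an estimated one. Dentate granule neuron markers lay lower. Of these, 9 of 10 had a negative change with a median of -0.24 (adjusted p = 0.000124, and 0.22 with an estimated correlation). Of these, 5 were lower when adjusted over the list alone. Npnt fell (-0.31, adjusted p = 0.0359), while Glis3 was at -0.29 (adjusted p = 0.0716) and Lct at -0.41 (adjusted p = 0.084). Interneuron markers lay higher. All 12 had a positive change with a median of 0.14 (adjusted p = 0.000101, and 0.107 with an estimated correlation), and 4 were higher when adjusted over the list alone. The serotonin receptor gene Htr3a rose from 5.16 ± 0.883 to 6.99 ± 0.799 RPKM (0.44, adjusted p = 0.0221). The GABA transporter gene Slc32a1 was at 0.29 (adjusted p = 0.0635) and Gad2, which makes GABA, at 0.27 (adjusted p = 0.109). Of the 23 interferon response genes 20 had a positive change with a median of 0.35 (adjusted p = 7.4e-07, and 0.271 with an estimated correlation), and 8 were higher and 1 lower when adjusted over the list alone. That median was 0.224 without WT F1. Ifit3b rose, the transcription factor gene Stat2 fell (-0.22, adjusted p = 0.0181), Oasl2 was at 0.57 (adjusted p = 0.0774) and H2-D1, whose reads can come from near-identical genes, at 0.44 (adjusted p = 0.109). Presynaptic vesicle release genes had a median of 0.07 with 16 of 19 positive (adjusted p = 0.0026, and 0.321 with an estimated correlation), and 1 was higher when adjusted over the list alone. Without WT M3 it was 0.0302. Rab3a was at 0.15 (adjusted p = 0.194). Cytosolic ribosomal protein genes, many with near-identical pseudogenes, had a median of -0.09 with 69 of 81 negative (adjusted p = 3.92e-06, and 0.771 with an estimated correlation) and 0 called when adjusted over the list alone. Rps23 was at -0.20 (adjusted p = 0.074) and Rps19 at -0.21 (adjusted p = 0.103). Markers of other tissue, none of these lists called, had medians of -0.25 (choroid plexus), -0.01 (myelin), 0.30 (ependyma, 7 of 7 positive, adjusted p = 0.0809), 0.26 (striatum, 6 of 9 positive, adjusted p = 0.0871) and 0.21 (cortex, 4 of 6 positive, adjusted p = 0.145).

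In all, limma called 202 genes in Dp16 against WT, 119 higher and 83 lower, and the authors' own adjusted p called 142, of which 122 were shared. The count was 48 in batch 1 alone and 65 in batch 2 alone, 116 without the WT library F1, 96 without the WT libraries F1 and M3, 97 without batch in the model and 94 with these groups alone in the fit. With libraries rescaled by their median ratio, 132 were higher and 55 lower. Without the WT libraries F1 and M3, 8 lists were called in place of 5.

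The comparison of the libraries labelled Dp16/D-KO with Dp16 asks what returning the Dyrk1a dose changes, although Dyrk1a itself was not lower there (-0.01; 0.02 in batch 1 and -0.03 in batch 2) and Kcnj6 was at -0.04 (adjusted p = 0.842). All 15 oligodendrocyte and myelin markers had a negative change, with a median of -0.44 (adjusted p = 4.21e-17, and 0.183 with an estimated correlation), and choroid plexus (-1.06) and ependymal markers (-0.57) had negative medians in the same libraries. S1pr5, a sphingosine phosphate receptor gene of oligodendrocytes, fell from 7.80 ± 1.61 RPKM in Dp16 (n = 7) to 5.03 ± 0.945 (n = 6; -0.59 ± 0.11 SE, adjusted p = 0.0362; -0.68 in batch 1 and -0.50 in batch 2) and the fatty acid desaturase gene Scd1 from 45.0 ± 4.6 to 34.6 ± 4.57 (-0.37, adjusted p = 0.047; -0.39 and -0.36). Trp53inp2, an autophagy gene, fell from 65.6 ± 2.27 to 54.9 ± 3.16 (-0.26, adjusted p = 0.0243) and Cln8, a lysosomal storage disease gene, from 7.51 ± 0.537 to 6.13 ± 0.591 (-0.30, adjusted p = 0.0243). Rfx5, a transcription factor gene of MHC class II expression, rose from 4.64 ± 0.482 to 6.12 ± 0.683 (0.40, adjusted p = 0.0243; 0.44 and 0.38). Eif4a1, a translation initiation factor gene, rose from 119 ± 2.5 to 133 ± 3.98 (0.15, adjusted p = 0.047) and Cyp11a1 from 1.18 ± 0.181 to 1.80 ± 0.225 (0.55, adjusted p = 0.047).

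The other called genes were Fbln7 (-0.83), Prr18 (-0.53), Krt9 (-0.53), Galnt6 (-0.49), Sema3c (-0.44), Shtn1 (-0.30) and Oxsr1 (-0.27), all lower, and Gadd45b (0.33), Pnrc2 (0.31), Bloc1s2 (0.30), Amt (0.28), Dimt1 (0.25) and Fbxo25 (0.23), all higher. For Cln8 and Dimt1 the authors' deposited table gives -0.18 and 0.13. The 20 calls, 9 higher and 11 lower, lay outside the segment.

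Of 33 lists, 9 were called with a preset correlation and 0 with an estimated one. The 15 oligodendrocyte and myelin markers were all lower when adjusted over the list alone, while 0 passed over all genes. Mbp, a major myelin protein gene, had 1068 ± 282 RPKM against 1521 ± 243 in Dp16 (-0.52, adjusted p = 0.0694). Opalin had 13.8 ± 3.34 against 21.3 ± 3.19 (-0.64, adjusted p = 0.0633) and Ugt8a 9.61 ± 2.12 against 14.1 ± 1.95 (-0.57, adjusted p = 0.0694). The list median was -0.55 in batch 1 and -0.32 in batch 2. Choroid plexus markers lay lower in the same libraries, and all 15 had a negative change with a median of -1.06 (adjusted p = 0.0049, and 0.643 with an estimated correlation), with 0 called when adjusted over the list alone. The choroid plexus median was -1.62 without Dp16 F1, and its call ended without Dp16 F2 (-0.73) or Dp16 M2 (-0.485). All 7 ependymal markers had a negative change with a median of -0.57 (adjusted p = 0.000396, and 0.564 with an estimated correlation), 2 of them lower when adjusted over the list alone. Tmem212 was at -0.88 (adjusted p = 0.137). The ependymal median turned positive with the myelin marker mean as a covariate.

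Interferon response genes lay lower, 19 of 23, with a median of -0.20 (adjusted p = 0.000608, and 0.643 with an estimated correlation), 1 lower when adjusted over the list alone. Ifit3b was at -0.43 (adjusted p = 0.132) and Irf7 at -0.49 (adjusted p = 0.181). Immediate early genes of neuronal activity lay higher, 21 of 22, with a median of 0.22 (adjusted p = 0.000396, and 0.643 with an estimated correlation). Fosb was at 0.50 (adjusted p = 0.178) and Nptx2 at 0.30 (adjusted p = 0.171). Circadian clock genes had a median of 0.11 with 13 of 15 positive (adjusted p = 0.00323, and 0.158 with an estimated correlation) and 4 higher when adjusted over the list alone. Per2 was at 0.28 (adjusted p = 0.0752) and Tef at 0.21 (adjusted p = 0.135). All 9 glucocorticoid response genes had a positive change with a median of 0.22 (adjusted p = 0.014, and 0.643 with an estimated correlation). Tsc22d3 was at 0.54 (adjusted p = 0.264). The call of this list ended without Dp16 F1 (median 0.156), Dp16 M4 (0.17), or the libraries F3 (0.184) or M1 (0.201) labelled Dp16/D-KO. Nuclear-encoded oxidative phosphorylation genes had a median of 0.05 with 58 of 80 positive (adjusted p = 0.0049, and 0.643 with an estimated correlation). Cox6a1 was at 0.18 (adjusted p = 0.14), and without the library F3 labelled Dp16/D-KO the median was 0.0449 and the call ended. Ribosomal protein genes had a median of 0.07 with 70 of 81 positive (adjusted p = 6.86e-05, and 0.643 with an estimated correlation) and 1 higher when adjusted over the list alone. Rpl27a was at 0.20 (adjusted p = 0.0515). Adjusted over the list alone, 0 immediate early, glucocorticoid response and oxidative phosphorylation genes were called.

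The count of 20 genes was 0 in each batch alone, without batch in the model, with the replicate label as a block and with the myelin marker mean as a covariate. With that covariate the 20 changes kept a median of 0.856 of their size, least in Prr18 (0.235), S1pr5 (0.341) and Galnt6 (0.352), and their SE grew by a median of 1.37 times. It was 89 without the WT libraries F1 and M3, which enter through the shared spread and covariates. It was 7 without the expression filter, 8 (2 higher and 6 lower) with quantile normalization, 62 with sex and batch of the WT libraries F1 and M3 as expression shows them, 52 with these groups alone in the fit and 219 with array quality weights. Rescaling by the median ratio gave 4 higher and 10 lower. It fell to 10 without Dp16 F1, 0 without Dp16 F2, 7 without Dp16 M1, 0 without Dp16 M2, 2 without Dp16 M3, and to 10, 9, 1 and 0 without the libraries F2, M1, M2 and M3 labelled Dp16/D-KO. The authors' adjusted p called 75 genes here, 15 of them shared.

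The comparison of the libraries labelled Dp16;D-KO/K-KO with those labelled Dp16/D-KO asks what returning the Kcnj6 dose in addition changes. Kcnj6 was at -0.02 (-0.12 in batch 1 and 0.06 in batch 2) and Dyrk1a at 0.03 (adjusted p = 0.899). The markers that lay lower in the libraries labelled Dp16/D-KO against Dp16 lay higher in this comparison, which shares those libraries. All 15 myelin markers had a positive change with a median of 0.43 (0.54 in batch 1 and 0.29 in batch 2; adjusted p = 6.35e-16, and 0.183 with an estimated correlation), and 14 were higher when adjusted over the list alone. Ugt8a had 13.8 ± 2.72 RPKM (n = 5) against 9.61 ± 2.12 (n = 6; 0.53, adjusted p = 0.243). All 15 choroid plexus markers had a positive change with a median of 2.02 (adjusted p = 2.07e-06, and 0.506 with an estimated correlation), with 0 called when adjusted over the list alone. All 7 ependymal markers had a positive change with a median of 0.79 (adjusted p = 1.86e-06, and 0.183 with an estimated correlation), 5 higher when adjusted over the list alone. Tmem212 was at 1.08 (adjusted p = 0.243) and Mia at 1.01 (adjusted p = 0.307).

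Limma called 0 genes in this comparison, 1260 had an unadjusted p under 0.05 where 699 fall there by chance, and the authors' adjusted p called 53. Of 33 lists, 14 were called with a preset correlation and 0 with an estimated one. Immature neuron and proliferation markers had a median of 0.17 with 7 of 8 positive (adjusted p = 0.00335, and 0.183 with an estimated correlation), 2 higher when adjusted over the list alone. Eomes was at 1.40 ± 1.45 against 0.275 ± 0.136 RPKM (1.59, adjusted p = 0.15) and Igfbpl1 at 0.66 (adjusted p = 0.243). All 9 oligodendrocyte precursor markers had a positive change with a median of 0.08 (adjusted p = 0.0306, and 0.183 with an estimated correlation), though the median was -0.00291 in batch 2 alone. Their call ended without M1 (0.0779) or M2 (0.07) labelled Dp16/D-KO and without F1 (0.0836), F2 (0.0531) or M2 (0.0736) labelled Dp16;D-KO/K-KO, and the median was 0.144 and 0.142 without F2 and M3 of the former and 0.166 without M3 of the latter. All 8 thalamus markers had a positive change with a median of 0.23 (adjusted p = 0.000589, and 0.183 with an estimated correlation), 2 higher when adjusted over the list alone. Zic1 was at 16.1 ± 12.5 against 3.75 ± 1.39 RPKM (1.77, adjusted p = 0.208) and Prkcd at 15.8 ± 3.95 against 9.96 ± 0.928 (0.63, adjusted p = 0.242). CA1 markers had a median of -0.13 with 6 of 7 negative (adjusted p = 0.0155, and 0.381 with an estimated correlation), a call that ended without M2 labelled Dp16/D-KO (-0.0732) and without F1 (-0.0705) or M2 (-0.102) labelled Dp16;D-KO/K-KO. All 5 erythroid markers were negative with a median of -0.38 (adjusted p = 0.0215, and 0.506 with an estimated correlation), and 19 of 23 interferon response genes were positive with a median of 0.11 (adjusted p = 0.0155, and 0.506 with an estimated correlation). The erythroid call ended without F2 (-0.298) or M1 (-0.317) labelled Dp16/D-KO and without F2 (-0.339), M2 (-0.382) or M3 (-0.285) labelled Dp16;D-KO/K-KO. The interferon call ended without F3 (0.0746) or M3 (0.0919) labelled Dp16/D-KO and without M1 labelled Dp16;D-KO/K-KO (0.0725), and its median was 0.186 without M3 so labelled.

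Immediate early genes had a median of -0.11 with 19 of 22 negative (adjusted p = 0.021, and 0.63 with an estimated correlation) and all 9 glucocorticoid response genes were negative with a median of -0.27 (adjusted p = 0.00208, and 0.506 with an estimated correlation). The immediate early call ended without M2 (-0.0404) or M3 (-0.0605) labelled Dp16/D-KO and without M1 (-0.0588) or M3 (-0.0683) labelled Dp16;D-KO/K-KO, and the median was -0.0722 and -0.0744 without F1 and M1 labelled Dp16/D-KO. That median turned slightly positive with the choroid plexus or the myelin marker mean as a covariate. Presynaptic genes had a median of -0.06 with 15 of 19 negative (adjusted p = 0.00345, and 0.338 with an estimated correlation), and of -0.035 without F1 labelled Dp16;D-KO/K-KO. Oxidative phosphorylation genes had a median of -0.06 with 71 of 80 negative (adjusted p = 2.47e-07, and 0.506 with an estimated correlation) and ribosomal protein genes of -0.03 with 66 of 81 negative (adjusted p = 0.00373, and 0.665 with an estimated correlation). The oxidative phosphorylation median was -0.0365 without M3 labelled Dp16;D-KO/K-KO. The ribosomal call ended without F3 labelled Dp16/D-KO (-0.0226) and without F1 (-0.0173) or M3 (0.0125, turned) labelled Dp16;D-KO/K-KO, and the median was -0.061 without M1 so labelled. In batch 1 alone the medians of the glucocorticoid, oxidative phosphorylation and ribosomal lists were 0.000995, 0.0462 and 0.0551. Adjusted over the list alone, 0 genes were called in 10 of the 14 called lists, all but the myelin, ependymal, immature neuron and thalamus lists. The gene count was 1 without the library M3 labelled Dp16;D-KO/K-KO, 1 with no filter or with these groups alone in the fit, 24 with array quality weights and 0 without the WT libraries F1 and M3.

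The comparison of the libraries labelled Dp16;D-KO/K-KO with Dp16 asks what returning both doses changes. All 5 genes called were higher. Rfx5 rose from 4.64 ± 0.482 RPKM (n = 7) to 6.56 ± 0.286 (n = 5; 0.49 ± 0.07 SE, adjusted p = 0.0123; 0.66 in batch 1 and 0.42 in batch 2). Pik3r3, a regulatory subunit gene of phosphoinositide kinase, rose from 9.14 ± 0.797 to 12.1 ± 1.52 (0.41, adjusted p = 0.0123; 0.55 and 0.34) and Rec8, a meiotic cohesin gene, from 0.71 ± 0.34 to 2.00 ± 0.467 (1.46, adjusted p = 0.0419; 1.83 and 1.15). Tmem181a, at 120 ± 24 against 66.4 ± 6.56 RPKM (0.85, adjusted p = 0.0123), and Dynlt1f, at 24.1 ± 5.82 against 12.5 ± 3.48 (0.95, adjusted p = 0.0123), overlap each other at 6256316 to 6655939 of chromosome 17, where near-identical copies of both genes lie, so the origin of their reads is uncertain. For Dynlt1f the authors' deposited table gives 0.44 here and 0.24 against WT. Dyrk1a was at 0.02 and Kcnj6 at -0.06.

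Circadian clock genes lay higher, the only list of 33 that kept its call with an estimated correlation in any of the 6 comparisons. Of these, 13 of 15 had a positive change with a median of 0.17 (adjusted p = 0.000431, and 0.0329 with an estimated correlation), and 7 were higher when adjusted over the list alone. The Dp16 libraries, which both corrected labels are compared with, lay below WT on this list, with a median of -0.097 and 12 of 15 negative (camera adjusted p = 0.0926, fry adjusted p = 0.0323), and the median of the libraries labelled Dp16;D-KO/K-KO against WT was 0.061 (camera adjusted p = 0.33). Against Dp16 the median was 0.20 in batch 1 and 0.08 in batch 2, and 0.103 without Dp16 M3. With an estimated correlation the call ended without Dp16 F3 (adjusted p = 0.0657), Dp16 M1 (adjusted p = 0.052), Dp16 M2 (adjusted p = 0.0754) or the library F1 labelled Dp16;D-KO/K-KO (adjusted p = 0.0766). Nr1d2, a repressor of the clock, had 19.3 ± 1.33 RPKM against 16.3 ± 1.41 (0.25, adjusted p = 0.103). Per2 had 9.85 ± 0.653 against 8.24 ± 0.728 (0.26, adjusted p = 0.18), Per3 10.7 ± 1.17 against 8.67 ± 1.75 (0.33, adjusted p = 0.192) and Tef 102 ± 10.7 against 88.2 ± 12.6 (0.22, adjusted p = 0.21). No label gives the hour of death. Interneuron markers had a median of -0.10 with 11 of 12 negative (adjusted p = 0.0037, and 0.159 with an estimated correlation). Htr3a was at -0.27 (adjusted p = 0.295), and the median was -0.0589 without the library M1 labelled Dp16;D-KO/K-KO. Presynaptic genes had a median of -0.07 with 16 of 19 negative (adjusted p = 6.18e-05, and 0.159 with an estimated correlation), 2 of them lower when adjusted over the list alone. Syp was at -0.12 (adjusted p = 0.207). Relatives of DYRK1A with its NFAT and cell cycle partners had a median of 0.12 with 12 of 16 positive (adjusted p = 0.0379, and 0.223 with an estimated correlation), 4 of them higher when adjusted over the list alone, the cyclin gene Ccnd2 at 0.26 (adjusted p = 0.073) and Ccnd1 at 0.24 (adjusted p = 0.17). The call of these relatives ended without Dp16 F1 (0.114), Dp16 M1 (0.0923), or the libraries F1 (0.104) or M2 (0.103) labelled Dp16;D-KO/K-KO. Clustered protocadherins, which share near-identical stretches, had a median of -0.10 with 36 of 55 negative (adjusted p = 0.0037, and 0.324 with an estimated correlation). Pcdhb11 was at -0.42 (adjusted p = 0.264), and the call of the list ended without M1 labelled Dp16;D-KO/K-KO (-0.0695). No interneuron marker or protocadherin was called when adjusted over the list alone. The choroid plexus median was 0.84 and the myelin median -0.04.

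The count of 5 genes was 1 in batch 1 alone, 0 in batch 2 alone, 2 without batch in the model, 10 (5 higher and 5 lower) with median ratio scaling, 30 with sex and batch as expression shows them, 16 with these groups alone in the fit, 57 with array quality weights and 7 without the WT libraries F1 and M3. It was 0 without F2, M1 or M2 and 2 without M3 of the libraries labelled Dp16;D-KO/K-KO, and the authors' adjusted p called 44 genes, 5 of them shared.

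The comparison of the libraries labelled Dp16/D-KO with WT asks what is left after the Dyrk1a correction. Of 79 segment genes, 76 were positive with a median of 0.55 (1.46-fold; 0.53 in batch 1 and 0.55 in batch 2; camera p = 7.01e-13 with an estimated correlation). Of these, 61 were called, all higher, and 69 when adjusted over the list alone. Dyrk1a rose by 0.51 (adjusted p = 1.22e-07; 0.56 and 0.47) and Kcnj6 by 0.51 (adjusted p = 0.000881; 0.51 and 0.55). Outside the segment 56 genes were higher and 60 lower. The nonagouti gene a rose from 0.54 ± 0.118 to 3.65 ± 0.559 RPKM (n = 5 and 6; 2.56 ± 0.15 SE, adjusted p = 3.11e-10). Slc5a5 rose from 6.97 ± 0.57 to 12.2 ± 0.918 (0.85, adjusted p = 7.88e-05) and Wfs1 from 40.3 ± 5.37 to 55.9 ± 7.06 (0.49, adjusted p = 6.33e-05). The extracellular matrix genes Dcn and Col4a2 rose from 24.4 ± 3.31 to 36.9 ± 4.72 (0.61, adjusted p = 0.0199) and from 14.2 ± 2.05 to 21.3 ± 2.82 RPKM (0.56, adjusted p = 0.0125). Cbs fell from 16.0 ± 2.33 to 9.95 ± 1.7 (-0.70, adjusted p = 2.3e-05). Adamts4, a matrix protease gene, fell from 5.71 ± 1.16 to 3.50 ± 0.574 (-0.70, adjusted p = 0.0133).

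The other called genes with the largest changes were Selenov (1.38), Cmbl (0.65), Pcsk4 (0.61), March3 (0.52), the metallothionein gene Mt2 (0.52), Gpr39 (0.52) and Kazald1 (0.52), all higher. Called lower were Igfbpl1 (-0.88), Nipal4 (-0.77), Sbsn (-0.77), Enpp6 (-0.70), Trim59 (-0.65), Mcam (-0.62) and Ccl25 (-0.62). Gnb5, a G protein subunit gene in the list of partners of the channel, rose from 41.4 ± 2.77 to 47.8 ± 1.29 RPKM (0.20, adjusted p = 0.00891). Of 33 lists, 9 were called with a preset correlation and 0 with an estimated one. All 15 myelin markers were negative with a median of -0.45 (-0.64 in batch 1 and -0.32 in batch 2; adjusted p = 1.79e-12, and 0.404 with an estimated correlation), and 14 were lower when adjusted over the list alone. Ugt8a fell (-0.59, adjusted p = 0.0449). All 15 choroid plexus markers were negative with a median of -1.51 (adjusted p = 0.0127, and 0.919 with an estimated correlation), with 0 called when adjusted over the list alone. That call ended without WT M2 (-1.01), WT M4 (-1.06) or the library M2 labelled Dp16/D-KO (-1.19), and the median was -2.78 without WT F1. Dentate granule neuron markers had a median of -0.26 with 9 of 10 negative (adjusted p = 0.000838, and 0.404 with an estimated correlation), 7 lower when adjusted over the list alone. Glis3 fell (-0.35, adjusted p = 0.0297).

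CA1 markers had a median of 0.12 with 6 of 7 positive (adjusted p = 0.0121, and 0.41 with an estimated correlation). The median was 0.204 without WT F1 and 0.194 without WT M3, and the call ended without WT M2 (0.0796). Interneuron markers had a median of 0.08 with 10 of 12 positive (adjusted p = 0.0156, and 0.404 with an estimated correlation) and immature neuron markers of -0.24 with 6 of 8 negative (adjusted p = 0.0377, and 0.566 with an estimated correlation). Adjusted over the list alone, 1 CA1 and 2 interneuron markers were higher, and of the immature neuron markers 1 was higher and 5 lower. The interneuron call ended without WT M2 (0.0938) or WT M3 (0.0942), and the median was 0.131 without WT F2. The immature neuron call ended without WT F1 (-0.233), F2 (-0.23), M2 (-0.225) or M4 (-0.225), or without F2 (-0.23), M1 (-0.218) or M2 (-0.242) labelled Dp16/D-KO. All 5 erythroid markers were positive with a median of 0.44 (adjusted p = 0.0241, and 0.919 with an estimated correlation), with Hba-a1, which has a near-identical copy, at 0.54 (adjusted p = 0.279), and the median was -0.0734 in batch 1 alone. The erythroid call ended without WT F1 (0.372), M3 (0.346) or M4 (0.357), or without F2 (0.356) or M1 (0.372) labelled Dp16/D-KO, and the median was 0.722 without WT M2. Immediate early genes had a median of 0.14 with 21 of 22 positive (adjusted p = 0.013, and 0.919 with an estimated correlation), 1 higher when adjusted over the list alone. Nptx2 was at 0.43 (adjusted p = 0.0589). The immediate early median was 0.285 without WT F1, and its call ended without WT M2 (0.0165) or the library M2 labelled Dp16/D-KO (0.0755). Oxidative phosphorylation genes had a median of 0.04 with 54 of 80 positive (adjusted p = 0.0121, and 0.919 with an estimated correlation), and like the erythroid markers had 0 called when adjusted over the list alone. Their call ended without WT F1 (0.0245), M2 (0.029) or M4 (0.0288) or the library F3 labelled Dp16/D-KO (0.0242), and the median was 0.0628 without WT M3. Limma called 179 genes, 119 higher and 60 lower, and the authors' adjusted p 142, of which 121 were shared. The count was 44 in batch 1 alone, 62 in batch 2 alone, 95 without batch in the model, 91 with these groups alone in the fit, 106 with the myelin covariate and 188 without the WT libraries F1 and M3. It was 387 without the WT library M3, 108 without WT M4, and 112 and 110 without the libraries F3 and M3 labelled Dp16/D-KO.

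The comparison of the libraries labelled Dp16;D-KO/K-KO with WT asks what is left after both corrections. All 79 segment genes were positive with a median of 0.55 (1.47-fold; 0.57 in batch 1 and 0.53 in batch 2; camera p = 1.49e-13 with an estimated correlation). Of these, 63 were called higher, and 74 when adjusted over the list alone. Dyrk1a rose by 0.54 (adjusted p = 1.46e-07; 0.53 and 0.56) and Kcnj6 by 0.49 (adjusted p = 0.00287; 0.39 and 0.61). Outside the segment 19 genes were higher and 21 lower. The nonagouti gene a rose to 4.59 ± 0.81 RPKM (n = 5; 2.87 ± 0.15 SE, adjusted p = 1.29e-10). Selenov rose to 1.11 ± 0.437 (1.69, adjusted p = 4.06e-05), Slc5a5 to 11.1 ± 0.663 (0.66, adjusted p = 0.00346) and Col4a2 to 21.8 ± 4.16 (0.60, adjusted p = 0.01). Cpne5, a calcium-binding copine gene, rose from 10.9 ± 1.67 to 15.3 ± 2.47 (0.49, adjusted p = 0.000459). Trpc6, a cation channel gene and dentate granule neuron marker, fell from 7.57 ± 0.872 to 5.16 ± 0.657 (-0.55, adjusted p = 0.0424). Cbs fell from 16.0 ± 2.33 to 11.8 ± 3.18 (-0.47, adjusted p = 0.00858; -0.15 in batch 1 and -0.57 in batch 2).

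The other called genes with the largest changes were Rspo1 (0.81), Cacng5 (0.63), Col15a1 (0.62), Gpr153 (0.55), Cmbl (0.52) and D16Ertd472e (0.49), all higher, with Dynlt1f (0.72), whose reads are of uncertain origin. Called lower were Tm6sf2 (-0.90), Htra4 (-0.70), Chst9 (-0.59), Cdh9 (-0.40), Zfp772 (-0.35), Fgf10 (-0.33), Rfx3 (-0.30) and Mcts1 (-0.27). Wfs1 rose by 0.31 (adjusted p = 0.0283). Of 33 lists, 6 were called with a preset correlation and 0 with an estimated one. Dentate granule neuron markers had a median of -0.31 with 9 of 10 negative (adjusted p = 3.88e-06, and 0.117 with an estimated correlation), 7 lower when adjusted over the list alone. Npnt was at -0.33 (adjusted p = 0.0552). All 7 ependymal markers were positive with a median of 0.50 (adjusted p = 0.00784, and 0.726 with an estimated correlation), 1 higher when adjusted over the list alone. Mia was at 1.05 (adjusted p = 0.25). The ependymal call ended without WT M3 (0.17) or the library F1 labelled Dp16;D-KO/K-KO (0.414). All 8 thalamus markers were positive with a median of 0.18 (adjusted p = 0.0318, and 0.705 with an estimated correlation), 2 higher when adjusted over the list alone. Prkcd was at 0.60 (adjusted p = 0.144). The thalamus call ended without WT F2 (0.179), M2 (0.125) or M3 (0.0685), or the library M2 labelled Dp16;D-KO/K-KO (0.112). All 9 striatum markers were positive with a median of 0.20 (adjusted p = 0.0482, and 0.705 with an estimated correlation), a call that ended without WT F1 (0.176), F2 (0.257) or M3 (0.109), or without F1 (0.209), M2 (0.227) or M3 (0.201) labelled Dp16;D-KO/K-KO. Interferon response genes had a median of 0.28 with 20 of 23 positive (adjusted p = 0.000137, and 0.705 with an estimated correlation). H2-D1 was at 0.38 (adjusted p = 0.324) and Rtp4 at 0.37 (adjusted p = 0.259). Ribosomal protein genes had a median of -0.06 with 62 of 81 negative (adjusted p = 0.00184, and 0.972 with an estimated correlation), though it was 0.0887 in batch 1 alone. The ribosomal call ended without WT F2 (-0.0246) or M3 (-0.0173), or without F1 (-0.0355) or M3 (-0.00567) labelled Dp16;D-KO/K-KO. Rpl5 was at -0.19 (adjusted p = 0.243). Adjusted over the list alone, 0 striatum, interferon response and ribosomal protein genes were called. The choroid plexus median was 0.52 and the myelin median -0.01. Limma called 105 genes, 84 higher and 21 lower, and the authors' adjusted p 112, of which 85 were shared. The count was 52 in each batch alone, 63 without batch in the model, 55 with these groups alone in the fit and 84 without the WT libraries F1 and M3.

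**Figure D3:**
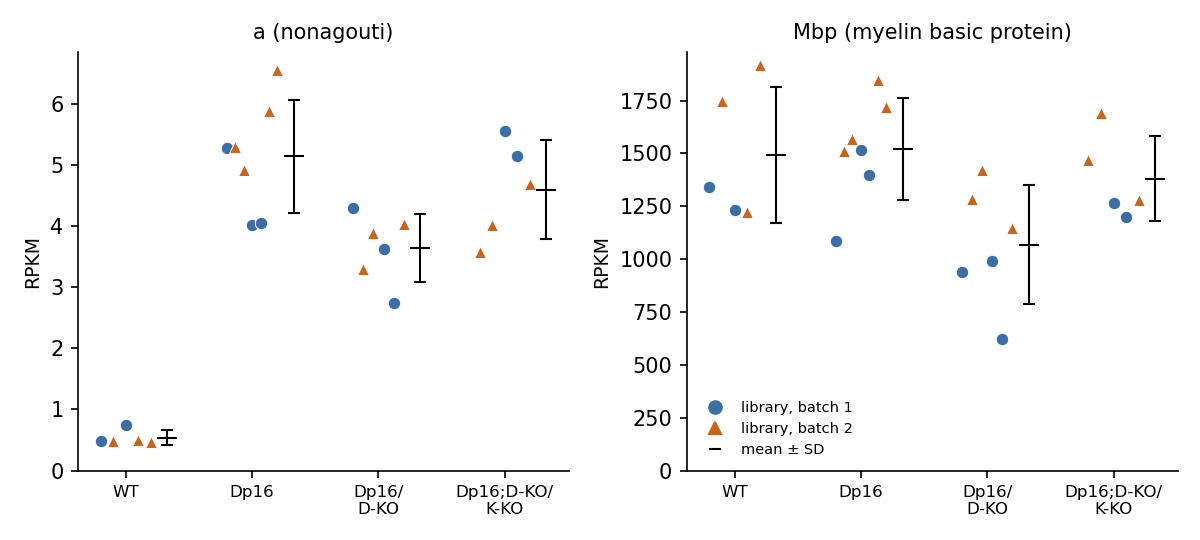
RPKM of the nonagouti gene a and of the myelin gene Mbp (vertical axes, from 0) in each of the 23 libraries by group as labelled, with batch 1 as circles, batch 2 as triangles and bars for the mean and SD. The nonagouti gene averaged 0.54 in WT and 5.14 in Dp16, and Mbp averaged 1068 in the libraries labelled Dp16/D-KO and 1521 in Dp16.

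Genes called outside the segment were compared between the contrasts with WT, which share their controls. Between Dp16 and the libraries labelled Dp16/D-KO, 14 higher and 9 lower genes were shared, against 0.214 and 0.359 expected of independent lists and 4 and 1.42 on average over 12 splits that gave each contrast its own, and so fewer, WT libraries. Between Dp16 and the libraries labelled Dp16;D-KO/K-KO, 11 higher and 5 lower were shared (3.33 and 0.583 with separate controls), and between the libraries of both corrected labels 11 and 6 (3.17 and 0.5). Over all 13890 genes outside the segment the changes correlated by 0.464, 0.560 and 0.358 in the same order, where simulated groups without change that share controls gave 0.555, 0.536 and 0.504, and with separate controls by -0.071, -0.035 and -0.104. Each covariance lay within the middle 95% of the simulated ones. In all 3 contrasts 9 genes were called higher, a, Wfs1, Selenov, Col4a1, Col4a2, Slc5a5, Cmbl, Cpne5 and D16Ertd472e, and 4 lower, Asprv1, Zfp772, Cbs and Rfx3. Of these, Col4a1 and Asprv1 fall outside the rule for named genes and were chosen after their values were seen. Whether the change from Dp16 runs back towards WT was measured as a covariance across the same 13890 genes, with separate Dp16 libraries in each difference. It was -0.00209 for the libraries labelled Dp16/D-KO (p = 0.242 in a one-sided permutation test of 1000 draws) and 0.000952 for those labelled Dp16;D-KO/K-KO (p = 0.421), so no return was detectable. The middle 95% of the permuted covariances ran from -0.0139 to 0.0112 and from -0.019 to 0.0137. A return whose covariance lies inside these ranges would not stand out, so the absence of a return is not shown. The covariance for the libraries labelled Dp16/D-KO was 0.0115 within batch 1 and 0.00021 within batch 2.

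The effect of the duplication was also compared between the sex letters and between the batches. Limma called 0 genes for the difference by letter, with 798 at an unadjusted p under 0.05, and 0 for the difference by batch, with 837, where 699 fall there by chance. The smallest adjusted p was 0.0737 by letter and 0.354 by batch. By letter the count was 1 without the WT library F1 and 2 without WT M3 or without both, and by batch it was 1 without WT M4 and 0 without the WT libraries F1 and M3.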

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

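The batch score, the tests of how many libraries carrying the duplication lie above WT, of the authors' scaling, of the lower bound for Dyrk1a, of the myelin list in the libraries labelled Dp16;D-KO/K-KO, the folds of the called genes under the myelin covariate, and the alternatives with a choroid plexus or myelin covariate, were chosen only after the results were seen.

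Of 310 sets of values, each a gene or the RPKM sum in 1 group, 17 had a library whose gap to the nearest other was a large share of the group's range. Chance gives about 1 in 20, and 17 is near that rate, so the flags as a whole are no more than chance can give. Far above and far below refer here to that share, not to the size of the gap. On the log2 scale the WT library M2 was far above the others for the nonagouti gene a (gap 0.8716 of the range) and F2 for Selenov (0.7362). The WT libraries F1 for Slc5a5 (0.9044), F2 for Glis3 (0.7582), M4 for Ctss (0.7387) and M3 for Adamts4 (0.854) were far below. In Dp16, F1 was far below for Slc5a5 (0.6607) and Eva1c (0.5799) and far above for D16Ertd472e (0.7572), M2 far above for Sh3bgr (0.7388), and M4 far above for Ncam2 (0.5722) and below for Lct (0.7012). Of the libraries labelled Dp16/D-KO, F1 was far below for Fbln7 (0.7257) and Mt2 (0.6942) and M3 for Cyp11a1 (0.6444). Of those labelled Dp16;D-KO/K-KO, M3 was far below for the choroid plexus gene Ttr (0.8272), which was chosen after its values were seen, and M1 far above for Mcts1 (0.8154).

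Ddx3y, a Y-linked gene outside the comparisons, stood at 12.65 RPKM in the WT library F1, while the other libraries with the letter F reached at most 0.03, and at 0.01 in the WT library M3. A score from 200 genes that differ between the batches in the other 3 groups ran from -0.0759 to 0.0695 in 8 batch 1 libraries and from 0.945 to 1.15 in 10 batch 2 libraries. It was 0.0866 in the WT library M3, which is labelled batch 2 but lies with batch 1, and 0.0568 in WT F1 and 0.90 in WT F2, each nearest to its labelled batch.

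The nonagouti gene a was higher in 18 of 18 libraries carrying the duplication than in the highest WT library. A stretch of another strain around the gene that changes several genes is argued against in Dp16 against WT, since 0 of 28 other tested genes within 1 Mb were called there. Of these 28, Trp53inp2 was at 0.0503 in Dp16 against WT (adjusted p = 0.639). It was called lower in the libraries labelled Dp16/D-KO than in Dp16 (-0.257, adjusted p = 0.0243). The nonagouti gene also had a lower mean in those libraries (3.645 against 5.14 RPKM), so the test does not cover that comparison. Choroid plexus in the pieces is also argued against, because the log2 change was 3.04 with the choroid plexus marker mean as a covariate. Whether a source of this transcript is carried with the duplication cannot be told apart from a strain difference that changes this gene alone, since the 18 of 18 libraries prompted the idea and go with either.

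Dyrk1a was not lower in the libraries labelled Dp16/D-KO than in Dp16. The authors' scaling is argued against, since the lower of its log2 changes under median ratio and quantile scaling was -0.0289. Whether these libraries are from Dp16 animals cannot be told apart. Of 100 splits of the 13 libraries only the real one, 1, called as many genes (20, against at most 1 in any other), which was set as evidence against it. The other splits were run under the main model alone, while the real count moved both ways under alternatives, so the question stays undecided. The count was higher than 20 with array quality weights and with these groups alone in the fit. It was also higher with the WT libraries F1 and M3 left out, or with their sex and batch as expression shows them. It was 0 with the replicate block, without batch in the model and in each batch alone. Without Dp16 F2, Dp16 M2 or the library M3 labelled Dp16/D-KO it was 0 too. With the myelin covariate it was also 0, as the SE of the genes grew by a median of 1.37 times, while their folds kept a median of 0.856 of their size (quartiles 0.691 to 1.08, and at most 0.352 in Prr18, S1pr5 and Galnt6), such as that of Rfx5 at 0.471 ± 0.095 SE after 0.397 ± 0.0693. Reads of a disrupted copy, if counted over the whole gene, cannot be told apart from those of an intact copy. The lower 95% bound of -0.0949 excludes a loss of a copy from the reads counted for the gene but says nothing of its exons.

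Myelin genes were lower in the libraries labelled Dp16/D-KO than in Dp16. Choroid plexus or ventricle wall in some pieces is argued against as the whole cause, since the median of the list was -0.42 with the choroid plexus covariate. Less white matter or fewer oligodendrocytes in the pieces may account for it: 100 genes outside the list that follow the myelin score in the other groups fell by a median of 0.557 of what their slope predicts (quartiles 0.243 to 0.811), and 84 were lower. These genes were picked by their correlation with the myelin score. Their fall therefore cannot tell fewer oligodendrocytes from lower expression of myelin genes in the same cells. The libraries labelled Dp16;D-KO/K-KO, which name the same removal of a Dyrk1a copy, did not share the fall, with a median of -0.0368 against Dp16. Whether that removal alone lowers these genes cannot be judged from this, since Dyrk1a was not detectably lower under either label. Measured Kcnj6 does not part the labels. On the log2 scale against WT it was raised by 0.51 in the libraries labelled Dp16/D-KO and by 0.49 in those labelled Dp16;D-KO/K-KO. Between them it differed by -0.02 (95% interval -0.20 to 0.15). These values argue against a different Kcnj6 level as part of the cause, unless reads of a disrupted copy are counted. The removal of a Dyrk1a copy together with such a hidden difference in Kcnj6 was not tested and stays open.

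Other splits of the same libraries, 100 per comparison with the real one among them, were tested for whether chance can give the counts. Few splits gave as many genes as the real one. In Dp16 against WT 3 splits did (202, and at most 344 in another). Against WT it was 2 splits each for the libraries labelled Dp16/D-KO (179, at most 386) and Dp16;D-KO/K-KO (105, at most 212). Against Dp16 it was 1 split for those labelled Dp16/D-KO (20, at most 1) and 3 splits for those labelled Dp16;D-KO/K-KO (5, at most 172). Chance is not excluded for the last 2 counts, since each fell to 0 when certain single libraries were left out. For the 3 counts against WT chance is unlikely but not excluded, since other splits called more genes. These 3 counts include 66, 63 and 65 called segment genes, which rise with the duplication itself. The splits were not run on the genes outside the segment alone, so they do not judge the calls made there. Splits that call more than the real ones point to a structure of the samples: that with 344 puts the WT libraries F2 and M3 with 5 Dp16 libraries, so that all 5 libraries on its other side have Ddx3y (10.56 RPKM or more) where 2 of these 7 do, and that with 386 exchanges the WT library M3 with the library F1 labelled Dp16/D-KO. That with 172 puts Dp16 F2 and M2 with the libraries F2, M1 and M2 labelled Dp16;D-KO/K-KO, the 5 of the 12 with the most Ttr (2316.86 RPKM or more, against at most 2009.44), and that with 212 puts the WT libraries F1, M2 and M4 with F1 and M3 of those. None of these follows the labelled batches. For the 0 genes called between the libraries of the corrected labels the splits decide nothing, since each of the 100 calls at least 0 (at most 6). Chance can be excluded for the segment medians of 0.52, 0.55 and 0.55 against WT (1 split in each; at most 0.434, 0.405 and 0.390). It cannot be excluded for the number of lists called in any of the 6 comparisons, in the order of the report 5 (73 splits; at most 15), 9 (43 splits; at most 16), 14 (7 splits; at most 17), 5 (73 splits; at most 17), 9 (21 splits; at most 12) and 6 (59 splits; at most 16).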

How the results depend on the processing

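The alternatives with the sex and batch of the WT libraries F1 and M3 as expression shows them, without those libraries, with a choroid plexus or myelin covariate, and with the circadian list at an estimated correlation with each library left out were chosen after seeing the data, and the others were planned. The rise of the segment and of Dyrk1a against WT kept its direction and its side of the threshold under every alternative run. Kcnj6 did so in Dp16, and kept only its direction in the libraries labelled Dp16/D-KO in batch 1 alone (0.512, adjusted p = 0.0813) and batch 2 alone (0.554, adjusted p = 0.0545), and in those labelled Dp16;D-KO/K-KO in batch 1 alone (0.391, adjusted p = 0.185). Among 116 results of called genes under the naming rule, each a gene in a comparison, 2239 values under alternatives lay on the same side of the threshold, 1063 kept the direction but not the call and 0 turned, and among 48 called list medians 1178 stayed, 273 lost the call and 11 turned. A fit by batch could not be given for the difference by batch, nor one without batch. Where no cause is named beside a value, the cause was not tested. Depth of 14.65 to 17.25 M reads and values rounded to 2 decimals limit genes of low level most, and no interval for it was computed.

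Genes called in Dp16 against WT (202) were 97 with no batch covariate, 48 in batch 1 alone and 65 in batch 2 alone (fewer libraries), 94 with only the compared groups in the fit, 96 without the WT libraries F1 and M3, and from 116 (without WT F1) to 274 (without WT M2) with each library left out. Lists called there (5) were 0 with an estimated correlation, 3 by fry, 8 without the WT libraries F1 and M3, and 5 to 9 with each library left out.

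For the libraries labelled Dp16/D-KO against Dp16 (20 genes), the count was 7 with no filter, 8 with quantile normalization, 0 with no batch covariate, 0 in batch 1 alone, 0 in batch 2 alone, 0 with the replicate block, 52 with only the compared groups, 219 with array quality weights, 62 with sex and batch as the expression shows, 89 without the WT libraries F1 and M3, 0 with the myelin covariate, and from 0 (without Dp16 F2, Dp16 M2 or the library M3 labelled Dp16/D-KO) to 26 (without Dp16 F3). Dyrk1a (-0.01) was 0.00242 with no batch covariate, 0.0173 in batch 1 alone, and -0.0234 to 0.0132 with each library left out. Lists called (9) were 0 with an estimated correlation, 2 by fry and 4 with the myelin covariate, under which the ependymal median was 0.14.

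For the libraries labelled Dp16;D-KO/K-KO against those labelled Dp16/D-KO (0 genes), the count was 1 with no filter, 1 with only the compared groups, 24 with array quality weights, and from 0 to 1 (without the library M3 labelled Dp16;D-KO/K-KO). Kcnj6 (-0.02) was 0.0604 in batch 2 alone, 0.0451 with the choroid plexus covariate, 0.0127 with the myelin covariate, and -0.0579 to 0.0249 with each library left out. Lists called (14) were 7 with quantile normalization, 5 with the myelin covariate, 0 with an estimated correlation and 0 by fry. Medians that turned were those of oligodendrocyte precursors in batch 2 alone (-0.00291), of the choroid plexus list with its own mean as covariate (-0.0636, by construction), of immediate early genes with the choroid plexus (0.000567) or myelin covariate (0.00981), and in batch 1 alone of glucocorticoid response (0.000995), oxidative phosphorylation (0.0462) and ribosomal genes (0.0551), the last at -0.061 to 0.0125 with each library left out.

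For the libraries labelled Dp16;D-KO/K-KO against Dp16 (5 genes), the count was 10 with median ratio scaling, 2 with no batch covariate, 1 in batch 1 alone, 0 in batch 2 alone, 16 with only the compared groups, 57 with array quality weights, 30 with sex and batch as the expression shows, and from 0 (without F2, M1 or M2 so labelled) to 7 (without Dp16 M3). Lists called (5) were 13 in batch 1 alone, 8 with the choroid plexus covariate, 1 with an estimated correlation, 2 by fry, and 4 to 8 with each library left out.

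Against WT, genes called in the libraries labelled Dp16/D-KO (179) were 95 with no batch covariate, 44 in batch 1 alone, 62 in batch 2 alone, 91 with only the compared groups, 106 with the myelin covariate, and from 108 (without WT M4) to 387 (without WT M3). Their lists (9) were 3 with array quality weights, 2 with the myelin covariate, 0 with an estimated correlation, 2 by fry, and 3 to 9 with each library left out, and the erythroid median was -0.0734 in batch 1 alone. Genes called in the libraries labelled Dp16;D-KO/K-KO (105) were 63 with no batch covariate, 52 in batch 1 alone, 52 in batch 2 alone and 55 with only the compared groups. Their lists (6) were 2 with array quality weights, 0 with an estimated correlation, 1 by fry, and from 2 (without WT M3) to 9 (without WT M4), and the ribosomal median was 0.0887 in batch 1 alone.

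With the replicate block the other counts were 199 in Dp16 against WT, 148 against WT in the libraries labelled Dp16/D-KO, and 75 against WT and 4 against Dp16 in those labelled Dp16;D-KO/K-KO, and 0 between the libraries of the corrected labels. The covariance with the libraries labelled Dp16/D-KO (-0.00209) was 0.0115 in batch 1 alone, 0.00021 in batch 2 alone, 0.00103 with the replicate block, 0.000424 with sex and batch as the expression shows, 0.00758 without the WT libraries F1 and M3, 0.00667 with the myelin covariate, and -0.0061 to 0.0028 with each library left out. With those labelled Dp16;D-KO/K-KO (0.000952) it was -0.00132 without the WT libraries F1 and M3, -0.0025 with the choroid plexus covariate, -0.0106 with all Dp16 libraries in both differences (by construction, since they are shared), and -0.00295 to 0.00308 with each library left out. The difference of Dp16 and WT by sex letter (0 genes) gave 1 with a pseudocount of 0.01, 1 with no filter, 1 with quantile normalization, 1 with the replicate block, 1 with array quality weights, 4 in batch 1 alone, 2 without the WT libraries F1 and M3, and 0 to 2 with each library left out (2 without WT M3). That by batch (0 genes) gave 3 with no filter and 0 to 1 with each library left out (1 without WT M4).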

Other observations

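Receptor and synapse lists that were tested but not called are given here as values in Dp16 against WT, and each was planned. The 21 glutamate receptor genes had a median log2 change of -0.000853 with 10 positive (adjusted p = 0.722), the 14 GABA receptor genes of 0.02 with 9 positive (adjusted p = 0.331), and the 19 postsynaptic density genes of 0.02 with 11 positive (adjusted p = 0.6). Partners of the Kcnj6 channel and other inward rectifiers, 16 genes, had a median of 0.06 with 9 positive (adjusted p = 0.347), with 3 higher and 1 lower when adjusted over the list alone. Of the other cell types, the 11 astrocyte markers had a median of -0.04 with 3 positive (adjusted p = 0.565), the 14 microglial markers of 0.01 with 7 positive (adjusted p = 0.347), and the 10 endothelial markers of -0.0015 with 5 positive (adjusted p = 0.985). The 8 immature neuron markers had a median of -0.17 with 2 positive (adjusted p = 0.287), and the 8 pericyte and smooth muscle markers of -0.13 with 1 positive (adjusted p = 0.411). Ependymal, striatum and cortex markers, also not called, are given in the report. The p-values are those of camera with the preset correlation.

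The choroid plexus gene Ttr ranged from 8.36 to 3760 RPKM over the 23 libraries and varied widely within groups. These values were chosen after they were seen.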
